A study of Homo sapiens and unidentified plasmid with 18 samples.

How the data were processed

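The series holds 18 samples of H1 human embryonic stem cells or of a plasmid library. Cells were transduced with pooled lentivirus, the medium was changed on day 1 and hygromycin selection began on day 2. Single cells were loaded for 10x Chromium 3′ v2 libraries, TF barcodes were amplified from cDNA to assign a construct to each cell, and gDNA of the remaining cells was taken for barcode counting. For the 11 single-cell samples the deposited tables hold raw UMI counts per gene and cell, and the authors' processing notes name Cell Ranger 2.0.0 and hg38. The gene annotation and the cell calling settings are not given in the sources used here. The barcode table holds raw read counts per TF and library as deposited, and the notes name MAGeCK. The construct assignments are of another kind of unit (other): the deposited lists give the cell barcodes assigned to each construct by the authors, with thresholds not given in the sources used here. Values were checked to be whole numbers that differ in total between cells and libraries.

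The per-sample tables of 33694 genes were used. The joined tables per screen hold the same cells and were not analysed here, nor were the gene modules the authors made from these libraries. The labels name replicates 2 and 3 of the hPSC screen, so only those were used. In NoHygro replicate 1, 532 assignment entries name cells absent from its count table and were left out. Totals ran from 39295895 to 76550670 UMIs in the libraries of the TF and neuronal screens, and 20518426 and 45019713 UMIs in the KLF and MYC tables. Cells with an assigned construct made up 59.2 and 57.4% in hPSC medium, 42.3 and 69.2% in endothelial medium, 26.2 and 49.3% in multilineage medium, 75.0 and 82.0% with the first neuronal vector and 38.5 and 33.4% with the NoHygro vector. In NoHygro replicate 1 the median mitochondrial share was 14.5%, against 1.91 to 5.39% in the other libraries. No cells were removed beyond the deposited tables in the main analysis. Doublets were not removed, so a set of several constructs can come from more than 1 cell in a droplet.

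Counts were summed over the cells of a genotype in a library (pseudobulk), so that libraries, not cells, were the replicates. In the TF screens only cells assigned to exactly 1 construct were used, and in the neuronal screens cells counted under their exact set of constructs. Genotypes needed at least 10 cells in each library. Genes were kept by filterByExpr by genotype, scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood F test (robust off) in a model with a library block and genotype, each genotype against mCherry cells of the same libraries. P-values were adjusted by Benjamini-Hochberg (BH) over all pairs of gene and genotype of a screen, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. All TFs of a screen share the same control cells, so genes called for several TFs are not independent. Differences of a TF effect between media were tested in the same way over the 6 TF screen libraries for the TFs named in any TF screen. Control cells of each library were compared between media in 1 fit of 6 sums and between vectors in 1 fit of 4 sums, without a block.

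For the 25 gene lists, fixed before the data were examined, limma 3.58.1 fry (two-sided directional test) was run on the same fits for lists with at least 3 measured members, with BH over all lists and genotypes of a screen, and camera with an estimated correlation beside it. Fry asks whether the members move on balance in 1 direction and does not compare a list with other genes. Members called over all genes and adjusted over the list alone were counted. Lists were run on the media and vector comparisons only after the data were seen. Barcode counts of the 7 gDNA libraries were tested with edgeR in 1 fit by medium, with the lone plasmid, endothelial and multilineage libraries assumed to vary like the 4 hPSC libraries. Fitness and the number of called genes were related over TFs with 100000 permutations, two-sided. The MYC and KLF sample, 1 library, was described without a test: CPM of summed counts with exact 95% Poisson intervals, and list medians against 10000 random lists matched on mean expression.

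The tests, groups, lists, named genes and most alternatives were fixed before the data were examined. Named genes in the TF screens are, for the 5 TFs with the most called genes, the 4 highest and the 1 lowest by log2 fold change among called genes that move alike in both libraries and reach 50 CPM in TF or control cells. The neuronal screens follow the same rule for 4 sets. In the medium comparisons they are the 8 highest and 8 lowest called genes with at least 100 CPM in the higher medium and no overlap of libraries. For fitness they are the 6 most depleted and 6 most enriched TFs, and for a called list of a named TF its 3 called members with the smallest p. Mitochondrial, ribosomal, antisense and clone-named genes were only counted. Some genes and sets that the rule selects are not described. A ratio against a control at 0 is given against a floor of 3 counts over the group, and one against 1 to 3 control counts with its exact 95% counting interval.

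The steps were tested on simulated data with the sizes of the real libraries. Of genes changed 4-fold, 81.6% were recovered in hPSC, 79.8% in endothelial and 84.0% in multilineage medium, 68.9% with the first neuronal vector and 79.4% with NoHygro; of genes changed 2-fold, 28.9, 23.3, 27.2, 30.4 and 35.5%. Between media 95.9% of 4-fold and 44.7% of 2-fold changes were recovered. With no TF effect, 7 of 363552 pairs were called in hPSC medium, 24 of 324114 in endothelial and 15 of 67236 in multilineage medium. In the real data, 20 random sets of control cells per TF screen were tested as if they carried a TF; between 2.71 and 4.86% of genes had p under 0.05.

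Alternatives were DESeq2 1.42.0 size factors and Wald test, limma voomLmFit with sample weights, no filter on low counts, no library block, a replicate block between media, at least 20 cells, BH within each genotype, all cells carrying a TF, all other single cells as reference, a cell filter (mitochondrial share of 20% at most, and within 3 median absolute deviations), other barcode scalings, summed libraries of a MOI, an MOI term, and each library left out in turn. Where 1 library was left out of a screen, the spread was taken from libraries of another medium or vector. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and data.table (version 1.17.8) were used.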

Results

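H1 human embryonic stem cells carrying a pooled lentiviral library of transcription factors (TFs) and an mCherry control construct were measured in 18 samples. The 11 single-cell RNA-seq samples held 2 libraries each of the TF screen in hPSC, endothelial and multilineage medium. They also held 1 sample of MYC forms and KLF family members in hPSC medium, and 2 libraries for each of 2 vectors of a combinatorial screen of neuronal TFs. The 7 gDNA samples held TF barcode counts from 4 hPSC libraries (2 at high and 2 at low MOI), 1 endothelial library, 1 multilineage library and the plasmid library.

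Cell numbers and depth differed between libraries. The hPSC libraries, replicates 2 and 3, held 3505 and 4223 cells with medians of 15985 and 16090 UMIs per cell. The endothelial libraries held 3563 and 6574 cells (15049 and 10682 UMIs), and the multilineage libraries 2129 and 4678 cells (27785 and 14527 UMIs). Cells assigned to exactly 1 construct numbered 1915 and 1678, 1245 and 3587, and 478 and 1868, of which 260 and 228, 131 and 477, and 64 and 289 carried mCherry. In the neuronal screen the first vector gave 6088 and 6089 cells (10188 and 8611 UMIs, 433 and 251 control cells), and the NoHygro vector 5795 and 5899 cells (6497 and 8942 UMIs, 277 and 237 control cells). The KLF and MYC tables held 1436 and 2735 cells and shared the same 223 control cells, 164 with mCherry and 59 with another control construct, mCherry-int-ctrl. Barcode libraries held 446317 and 664228 reads at high MOI, 790473 and 598240 at low MOI, 356486 in endothelial medium, 331231 in multilineage medium and 663275 for the plasmid. P-values of genes, lists and barcodes below measure only the spread between these libraries, in the screens what remains of it after the library block. The labels do not say whether replicates were separate cultures. Permutation p-values over TFs rest on the spread between TFs.

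The transcript of the overexpressed TF itself was called higher for few TFs. In hPSC medium HOXA11, a posterior HOX gene, rose by 7.60 (log2 fold change, SE 0.40) in HOXA11 cells, POU1F1 by 5.93 (SE 0.64) in POU1F1 cells and CDX2 by 4.39 (SE 0.90) in CDX2 cells, 2 libraries each. HOXA11 also rose in endothelial medium (5.79, SE 0.42) and multilineage medium (6.37, SE 0.81). In the NoHygro neuronal screen FOXA2 rose by 2.35 (SE 0.36) and SNAI2 by 4.15, and ASCL4 and LMX1A were called higher over a control listed at 0. Own transcripts had 0 counts in 20 of 51 constructs in hPSC medium, 19 of 59 in endothelial medium and 28 of 54 in multilineage medium. The libraries read the 3′ end of the lentiviral transcript, which need not hold the TF reading frame, so an absent own transcript checks nothing about the assignment.

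In hPSC medium KLF4, CDX2, SNAI2, MYOG and NEUROD1 changed the most genes against mCherry cells. KLF4 cells (80 cells) had 452 called genes, 323 higher and 129 lower. HAND1, a regulator of heart and extraembryonic mesoderm, rose by 7.20 (SE 0.43, adjusted p = 6.95e-27), with 304 and 34.6 CPM against 1.61 and 0.265 in control cells. MESP1, the earliest cardiac mesoderm factor, rose by 5.59 (SE 0.39), CDX1 by 4.82 (SE 0.46) and the matrix link protein HAPLN1 by 4.63 (SE 0.51), and PPP2R2B fell by 1.87 (SE 0.31). CDX2 cells (55 cells, 242 genes) expressed posterior HOX genes that the control nearly lacked: HOXB9 rose by 7.45 (SE 0.47) and HOXC6 by 6.53 (SE 0.44). HOXC8 was listed at 0 in the control and at least 144-fold higher against a floor of 3 counts over the group. HOXB7 had 3 control counts and a ratio of 281 (counting interval 93.4 to 1390). The WNT receptor gene FZD7 fell by 3.26 (SE 0.40) in CDX2 cells.

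SNAI2, a repressor of epithelial genes, gave 143 called genes in 125 cells in hPSC medium, 50 higher and 93 lower. VIM, the mesenchymal intermediate filament, rose by 2.00 (SE 0.23), D21S2088E by 1.36 (SE 0.22), the secreted WNT antagonist SFRP1 by 1.05 (SE 0.19) and GYPC by 1.03 (SE 0.16). MAL2, an apical transport protein of epithelia, fell by 1.70 (SE 0.19). MYOG cells (100 cells, 98 genes) gained the fast skeletal muscle myosin light chain MYLPF (4.43, SE 0.37), TFF3 (3.53, SE 0.35), SHISA2 (2.77, SE 0.23) and RGS16 (2.20, SE 0.28), and the metallothionein MT1X fell by 1.70 (SE 0.22). NEUROD1 cells (30 cells, 84 genes) gained STMN2, a microtubule regulator of neurons (7.73, SE 0.50), HAPLN1 (5.61, SE 0.59), CAMK2N1 (4.47, SE 0.37) and PRTG (4.27, SE 0.62). The PRTG value rests on replicate 3, with log2 fold changes of 0.37 and 4.24 in the libraries. FAM101B fell by 1.74 (SE 0.43, adjusted p = 0.0277) in NEUROD1 cells, a call kept in 4 of 11 alternatives.

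Fixed gene lists placed these changes in programs of hPSC medium. In KLF4 cells the mesendoderm list had a median log2 fold change of 3.40: 8 of 11 measured members rose over all genes and 9 adjusted over the list alone (fry adjusted p = 1.07e-19), among them MIXL1 (3.73) and LEFTY2 (3.40). All 4 measured trophoblast members rose (median 4.24; GATA2 5.74, TFAP2C 2.05), and 8 of 18 epithelial genes (11 adjusted over the list alone; KRT8 2.27, KRT18 1.97, DSP 1.80). The pluripotency list fell (median -0.418; 7 of 17 lower and 2 higher; 10 lower adjusted over the list alone), with TERF1 at -1.57 and USP44 at -1.65 but DPPA2 at 3.26. In CDX2 cells all 3 measured HOX members rose (median 6.52, with HOXB6 at 5.58, SE 0.58). The HOX list has 14 members and the trophoblast list 18. A member near 0 in the control can be measured only because TF cells express it. These and other shares of measured members that rose are thus in part set by the filter on low counts. SNAI2 cells lost epithelial genes (median -0.621; 6 of 18 over all genes, 10 adjusted over the list alone; CLDN7 -1.38, EPCAM -1.36; adjusted p = 1.47e-05). MYOG cells gained the BMP and ID list (median 1.09; 5 of 8; 6 adjusted over the list alone; ID2 1.69, ID4 2.02, ID3 1.14) and mesendoderm genes (2 of 11; 6 adjusted over the list alone; EOMES 2.05, CER1 2.98). NEUROD1 cells gained the neuronal list (median 2.34; 5 of 7; 6 adjusted over the list alone; DLL3 3.88, GADD45G 2.34).

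The edgeR quasi-likelihood test over 8224 genes and 49 TFs in hPSC medium called 1955 of 402976 gene and TF pairs, 1490 higher and 465 lower. There 25 TFs had at least 20 called genes, and 3 had none. With 1 library left per genotype far fewer pairs were called, 286 without replicate 2 and 299 without replicate 3. KLF4 then had 51 and 124, CDX2 47 and 40, SNAI2 3 and 1, MYOG 13 and 14, and NEUROD1 41 and 6. Random sets of control cells of the size of a typical TF gave at most 4 calls at the same cutoff in 20 draws. Over the fixed lists, fry called 62 of 1078 list and TF pairs, 45 higher and 17 lower. The mesenchymal list (0.116) in SNAI2 cells was among those lost with an estimated correlation (adjusted p = 0.143 with an estimated correlation), as was the pluripotency list in CDX2 cells (-0.378; adjusted p = 0.0756 with an estimated correlation), and 46 pairs were kept by both tests.

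**Figure D1:**
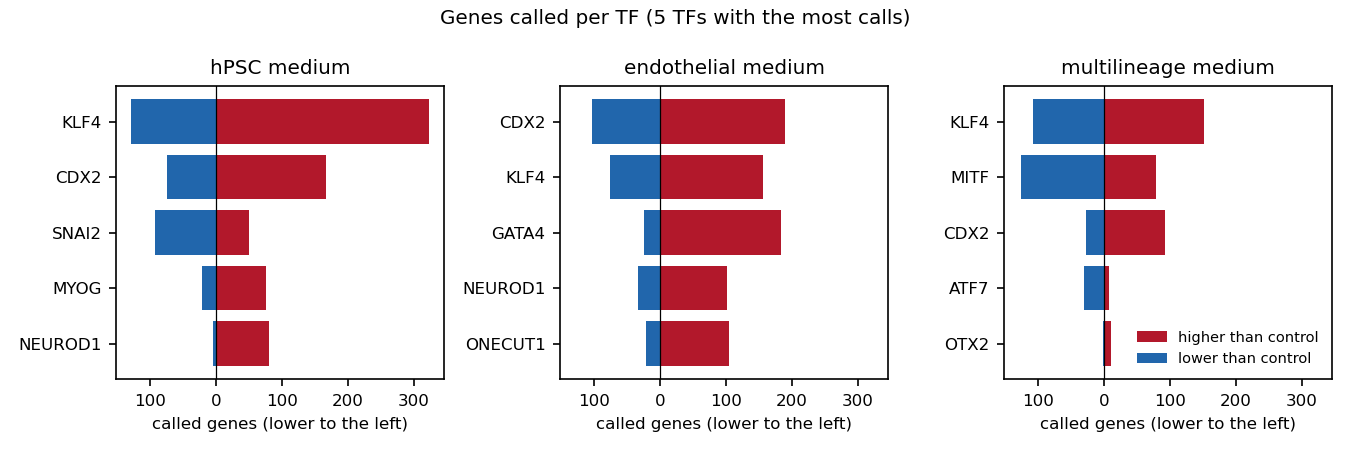
Number of called genes (x axis) for the 5 TFs with the most calls (y axis) in the 3 media, bars to the right for genes higher and to the left for genes lower than in mCherry cells. KLF4 had 452 called genes in hPSC, 232 in endothelial and 258 in multilineage medium.

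In endothelial medium CDX2 again had posterior HOX genes among its strongest gains: HOXB8 rose by 5.65 (SE 0.45) and HOXC6 by 4.84 (SE 0.50) in 188 cells with 292 called genes, 189 higher and 103 lower. The matrix protein gene TGFBI rose by 4.51 (SE 0.33), C6orf15 by 5.10 (SE 0.39), and the NODAL co-receptor TDGF1 fell by 2.14 (SE 0.24). The C6orf15 value rests mostly on replicate 2 (0.51 and 4.61 in the libraries), and TGFBI also rose more there (1.88 and 4.55). KLF4 cells (257 cells, 232 genes) gained ABHD12B (4.35, SE 0.29), LIM2 (3.96, SE 0.35), S100A14 (2.86, SE 0.32) and the tissue factor gene F3 (2.74, SE 0.33). S100A14 stood at 1.26 and 3.53 in the libraries. GATA4 cells (80 cells, 208 genes) gained the cystatins CST4 (5.67, SE 0.38) and CST1 (5.56, SE 0.44), the HDL protein gene APOA1 (5.31, SE 0.46) and DIO3, a thyroid hormone deiodinase (5.24, SE 0.41). APOA1 rose more in replicate 2 (1.84 and 5.11 in the libraries). POLR3G fell by 2.08 (SE 0.35) in GATA4 cells.

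NEUROD1 cells in endothelial medium (49 cells, 135 genes) gained SUSD2 (6.05, SE 0.69), PSTPIP1 (5.66, SE 0.71) and PCP4 (5.34, SE 0.89), the last mostly from replicate 2 (0.33 and 4.68 in the libraries). TNNI1, the slow skeletal troponin I, had 3 control counts and a ratio of 143 (counting interval 44.1 to 738), mostly from replicate 2 (3.87 and 111 CPM in the libraries), and the alkaline phosphatase gene ALPL fell by 1.85 (SE 0.46, adjusted p = 0.0324), a call kept in 4 of 11 alternatives. ONECUT1 cells (89 cells, 126 genes) gained LGR5, a receptor for R-spondins (6.36, SE 0.59), FGF18 (5.19, SE 0.48), the NOTCH effector HEY1 (4.66, SE 0.44) and HAPLN1 (4.53, SE 0.53). POU5F1B fell by 1.80 (SE 0.36) in ONECUT1 cells. Values of POU5F1B, a near-identical copy of POU5F1, and of the closely related cystatins are uncertain, as short reads do not always separate such copies.

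In GATA4 cells of endothelial medium 6 of 7 liver and endoderm genes rose (median 4.19, and 4.19 with TTR, listed at 0 in the control, at its bound; 6 adjusted over the list alone; APOA1 5.31, CXCR4 3.41; adjusted p = 1.04e-14), and 6 of 8 mesendoderm genes (median 3.20; EOMES 3.14, LHX1 3.25, CER1 2.74). Cardiac genes rose in GATA4 cells under fry (3 of 5; median 2.90; MYL7 2.90, NPPB 3.61, MYL4 3.46; adjusted p = 0.171 with an estimated correlation). NEUROD1 cells gained 6 of 8 neuronal genes (median 2.87; 7 adjusted over the list alone; HES6 3.18, DLL3 3.78, SRRM4 4.91). KLF4 cells gained trophoblast genes (median 1.47; 4 of 9 higher and 1 lower, 5 higher adjusted over the list alone; HAND1 3.77, KRT7 1.83), and CDX2 cells lost pluripotency genes (median -0.715; 7 of 17, 10 adjusted over the list alone; TDGF1 -2.14, USP44 -1.50, POU5F1 -1.14; adjusted p = 0.359 with an estimated correlation).

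The test in endothelial medium over 8482 genes and 43 TFs called 1753 pairs, 1370 higher and 383 lower. There 15 TFs had at least 20 called genes and 4 had none. Without replicate 2 of this medium 1093 pairs were called, 110 for CDX2, 119 for KLF4, 91 for GATA4, 54 for NEUROD1 and 28 for ONECUT1. Random sets of control cells gave at most 5 calls in 20 draws. Of 989 list and TF pairs, fry called 35, 30 higher and 5 lower, and 23 were called with both tests.

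In multilineage medium KLF4 cells (98 cells) had 258 called genes, 151 higher and 107 lower. S100A14 rose by 6.83 (SE 0.55), NLRP7 by 5.84 (SE 0.59) and CDX1 by 5.23 (SE 0.49), and the keratin gene KRT6A, listed at 0 in the control, was at least 93.2-fold higher, mostly from replicate 2 (8.48 and 95.9 CPM in the libraries). The BMP antagonist GREM1 fell by 2.16 (SE 0.40). MITF, the melanocyte regulator, had 205 called genes in 17 and 10 cells, 79 higher and 126 lower: CARD16 rose by 3.01 (SE 0.43), the peptidase gene MME by 2.73 (SE 0.41), HSBP1L1 by 2.72 (SE 0.37) and SPANXB1 by 2.5 (SE 0.60), and F3 fell by 2.46 (SE 0.59, adjusted p = 0.0319), kept in 5 of 11 alternatives. The SPANXB1 value rests on replicate 2 (0.09 and 2.58 in the libraries). CDX2 cells (70 cells, 120 genes) gained C15orf48 (5.45, SE 0.45), the chemokine CXCL14 (3.47, SE 0.41) and TM4SF1 (3.38, SE 0.45), and the aggrecanase gene ADAMTS5 fell by 2.05 (SE 0.34). CXCL14 stood at 4.45 and 2.15 in the libraries. LEFTY2, a NODAL inhibitor, had 3 control counts and a ratio of 146 in CDX2 cells (counting interval 48.1 to 722).

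ATF7 cells in multilineage medium (30 cells, 37 genes) gained HIST1H2BG (2.02, SE 0.44), QRICH1 (1.35, SE 0.33), PEF1 (1.20, SE 0.20) and SAC3D1 (1.08, SE 0.27). SLC7A11, the cystine transporter, fell by 2.80 (SE 0.64, adjusted p = 0.0235) in ATF7 cells. Of 11 alternatives 4 kept the call of QRICH1 and 5 those of SAC3D1 and SLC7A11. OTX2 cells (35 cells, 11 genes) gained HAND1 (2.95, SE 0.61), CCDC80 (2.06, SE 0.34), the immediate early gene EGR1 (2.01, SE 0.49) and the myelin protein gene PMP22 (1.84, SE 0.38). PMP22 rests on replicate 1 (2.72 and 0.14 in the libraries) and EGR1 mostly so (2.29 and 0.73). Of 11 alternatives 4 kept the call of EGR1, 6 that of HAND1 and 7 that of PMP22. In KLF4 cells 8 of 10 trophoblast genes rose (median 1.76; 8 adjusted over the list alone; GATA2 3.31, HAND1 4.57, VGLL1 3.11; adjusted p = 3.39e-08), the only pair of 247 that was also called with an estimated correlation. Epithelial genes fell in MITF cells (median -0.888; 3 of 17, 10 adjusted over the list alone; KRT18 -1.40; adjusted p = 0.281 with an estimated correlation), and so did the mesenchymal (median -0.688, adjusted p = 0.212) and neural progenitor lists (-0.760, adjusted p = 0.293). In CDX2 cells the mesendoderm list had a median of -0.891 while fry called it higher, since LEFTY2 alone rose (adjusted p = 0.630 with an estimated correlation).

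The test in multilineage medium over 6281 genes and 13 TFs called 652 pairs, 351 higher and 301 lower. There 4 TFs had at least 20 called genes and 1 had none. Without replicate 1 of this medium 306 pairs were called, 108 for KLF4, 88 for MITF, 59 for CDX2 and 23 for ATF7. Without replicate 2 ATF7 had 69 and OTX2 17. Random sets of control cells gave at most 2 calls in 20 draws. Fry called 8 list and TF pairs, 4 higher and 4 lower.

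Some TF effects differed between media by a direct test. In NEUROD1 cells STMN2 lay 7.73 above the control in hPSC medium and 1.99 above it in endothelial medium, a difference of -5.92 (SE 0.86, adjusted p = 9.54e-05), with CAMK2N1 (-3.35, SE 0.69) and PRTG (-3.48, SE 0.84) in the same direction. Without hPSC replicate 3 these stood at -5.41, -1.97 and 0.06, and none was called. PRTG was called in 1 of the 6 fits with 1 library left out. In KLF4 cells 41 of 44 such genes responded lower in endothelial than in hPSC medium, among them the mesendoderm genes CER1, LEFTY1 and LHX1. In multilineage medium KLF4 responses were lower for MESP1 (-6.32, SE 1.38), HAPLN1 (-4.63, SE 0.94) and F3 (-2.38, SE 0.43) and higher for 60 of 170 genes, among them the replication genes GINS2, MCM4 and RRM2 (list members were chosen here after their values were seen). CDX2 responses in multilineage medium were lower for HOXB7 (-5.59, SE 1.04) and ADAMTS5 (-4.62, SE 1.07) and higher for LEFTY2 (4.90, SE 0.94), and the OTX2 response was higher for CCDC80 (3.6, SE 0.80). Without hPSC replicate 2 MESP1 stood at -5.54, HAPLN1 at -3.27, F3 at -2.54, HOXB7 at -5.64, ADAMTS5 at -4.90, LEFTY2 at 5.80 and CCDC80 at 3.50. Without hPSC replicate 3 they stood at -7.07, -4.93, -2.29, -5.64, -4.43, 4.41 and 3.65. Every gene given with a value here lost its call in the fit without hPSC replicate 2, the fit without hPSC replicate 3, or both. The list members named without a value are not covered by this. Without multilineage replicate 2 HAPLN1 stood at -2.84, MESP1 at -8.04, HOXB7 at -4.65, LEFTY2 at 4.68 and CCDC80 at 3.97, and without replicate 1 MESP1 at -6.07, ADAMTS5 at -4.43 and CCDC80 at 3.46, none of these called.

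Over 9259 genes and 9 TFs, 400 of 129626 interaction pairs passed, 101 between endothelial and hPSC medium and 299 between multilineage and hPSC medium. By TF the endothelial comparison gave KLF4 44, CDX2 25 and ONECUT1 15, and the multilineage comparison KLF4 170, CDX2 55, MITF 44 and ATF7 21. With 1 library left out these ran from 3 to 82, 1 to 79 and 1 to 34, and from 9 to 261, 8 to 99, 4 to 114 and 2 to 52. The total was 39 without hPSC replicate 2, 80 without hPSC replicate 3 and 708 without endothelial replicate 1. On simulated data this test recovered 27.3% of 4-fold differences, so genes outside the 400 are not shown to respond alike. The labels give a high estimated MOI for the hPSC libraries and a low one for the others, though of assigned cells 7.67 and 30.7% carried several constructs in hPSC replicates 2 and 3 and 14.2 to 21.2% in the others, so an MOI effect was not separated from that of the medium.

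Control cells themselves differed between media. Against hPSC medium, control cells in endothelial medium had these genes higher: ANXA1 rose by 5.23, VIM by 4.74 (SE 0.52), LGALS1 by 4.72, PRSS23 by 4.54, SPP1 by 3.76, CTGF by 3.48 and SFTA1P by 7.48. Genes that fell were the telomere protein gene TERF1 (-1.42, SE 0.23), the DNA methyltransferase DNMT3B (-1.12), USP44 (-0.99), DPPA4 (-0.98), SKIL (-1.31), ZNF770 (-1.11), HELLS (-1.04) and PKIB (-1.0). Of 10 alternatives 9 kept the calls of TERF1 and SKIL, 8 that of ZNF770 and 6 that of PKIB. The calls of DNMT3B, USP44, DPPA4 and HELLS were kept in 7. In multilineage medium, against hPSC medium, DNMT3B fell by 4.58 (SE 0.29), SOX2 by 4.18 (SE 0.38), TERF1 by 4.08, VRTN by 4.08 and TDGF1 by 3.75, and the cycle genes PIF1, KIAA0101 and HIST1H4C by 3.07, 3.02 and 2.91. The natriuretic peptide gene NPPB rose by 8.98 (SE 0.66), IGFBP7 by 8.05, GLIPR1 by 7.83, IGFBP5 by 7.81, LOX by 7.57 and SFTA1P by 8.39. DIO2 (2 hPSC counts) had a ratio of 406 (counting interval 112 to 3360) and MFAP5 (3 hPSC counts) of 376 (128 to 1830).

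Between the differentiation media, control cells in endothelial medium had more SOX2 (3.67), DNMT3B (3.46), KIAA0101 (3.20), NASP (3.00), TDGF1 (2.96), APOC1 (2.89), SFRP2 (2.83) and SEPHS1 (2.82). They had less DIO2 (-5.81), IGFBP3 (-4.38), INHBA (-3.37), IGF2 (-3.28), NKAIN4 (-3.26), MFAP5 (-3.19), NPPB (-3.14) and IGFBP5 (-3.10). The pluripotency list, tested here only after the values were seen, fell for 18 of 18 genes from hPSC to multilineage medium (median -2.44; adjusted p = 0.00547; at least 0.2 for every list with an estimated correlation). In the same test p53 targets rose (10 of 12; median 2.18) and S phase genes fell (13 of 15; median -1.84). Cardiac (6 of 6, median 4.75), trophoblast (9 of 11, 4.51), mesenchymal (14 of 17, 4.36), liver and endoderm (4 of 4, 2.72) and stress genes (7 of 12, 1.46) rose too. Mitochondrially encoded genes fell (10 of 13, -0.773). The epithelial (10 of 20, 0.753), BMP and ID, hypoxia and skeletal muscle lists also passed as higher. The cholesterol (12 of 12, -1.24), G2M and MYC target lists passed as lower. As 5136 of 12307 genes were called here and fry does not compare a list with other genes, these lists are not set apart from the rest. No list passed fry between endothelial and hPSC medium (lowest adjusted p = 0.0589).

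**Figure D2:**
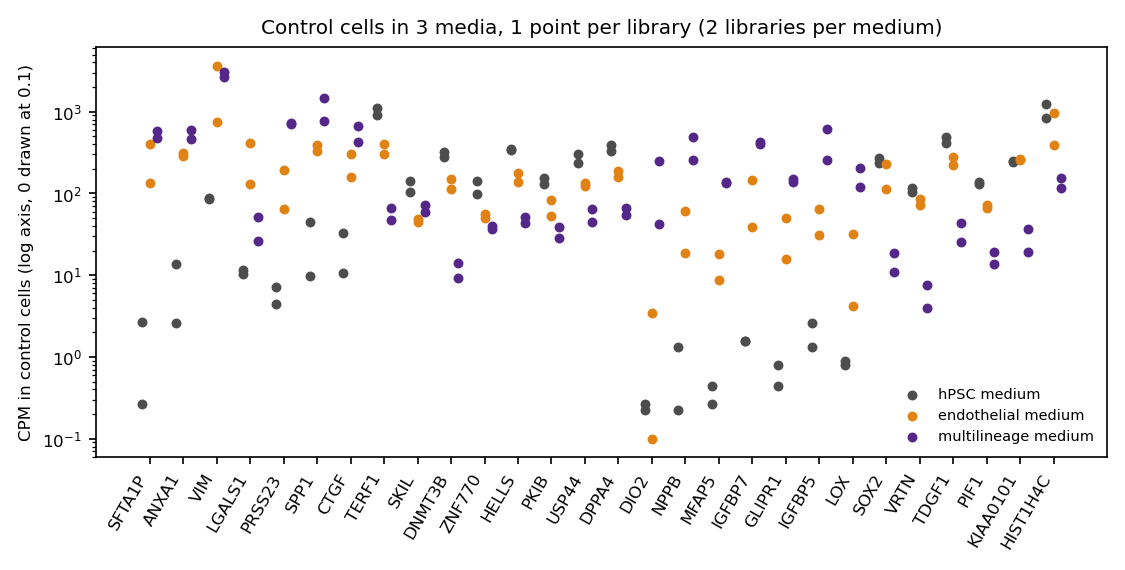
CPM (y axis, log scale, 0 drawn at 0.1) of genes (x axis) named for the medium comparisons in control cells, 1 point per library and 2 libraries per medium. DNMT3B lies at 277 and 323 CPM in the hPSC libraries and at 150 and 112 CPM in the endothelial libraries.

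The medium test over 12307 genes called 1023 genes between endothelial and hPSC medium (766 higher, 257 lower), 5136 between multilineage and hPSC medium (2623 higher, 2513 lower) and 2775 between endothelial and multilineage medium (1408 higher, 1367 lower). Groups did not overlap for 1006, 5128 and 2766 of them. Chance gives this for 33.3% of unselected genes with 2 libraries against 2. These genes were called on the same libraries, so the lack of overlap adds no support. The first count was 258 without hPSC replicate 2, 146 without hPSC replicate 3 and 347 without endothelial replicate 2, and the second 3020 without multilineage replicate 2. The third was 1806 without endothelial replicate 1, 1742 without multilineage replicate 1 and 1114 without multilineage replicate 2.

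In the neuronal combinatorial screen with the first vector, NEUROG3 cells (647 cells, 448 genes) gained HOPX (3.87, SE 0.40), the microfibril gene MFAP4 (2.70, SE 0.24), the atrial myosin light chain MYL4 (2.68, SE 0.27) and GYPB (2.63, SE 0.31), and B3GNT7 fell by 1.55 (SE 0.25). MITF cells (196 cells, 294 genes) gained GDF15, a p53-responsive stress cytokine (3.82, SE 0.30), SFTA1P (3.50, SE 0.43), IGFBP7 (3.42, SE 0.33) and ANKRD1 (3.14, SE 0.39), and CLDN10 fell by 2.20 (SE 0.60, adjusted p = 0.0432). SNAI2 cells (569 cells, 254 genes) gained CER1 (2.04, SE 0.33), ENC1 (1.82, SE 0.23), RSPO3 (1.81, SE 0.25) and DKK1 (1.66, SE 0.35), and the tight junction gene CLDN7 fell by 2.16 (SE 0.25). NEUROD1 cells (191 cells, 223 genes) gained the embryonic globin HBE1 (6.41, SE 0.52), IGF2 (4.74, SE 0.45), PGA5 (4.44, SE 0.36) and HOPX (4.25, SE 0.45), and CDA fell by 1.24 (SE 0.32).

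Lists in this vector moved in many genotype sets. In NEUROG3 cells all 3 measured HOX members rose (median 2.30, HOXB2 2.41, HOXB6 2.30). Of 14 mesenchymal genes 9 rose and 1 fell in these cells (median 1.15, COL1A2 1.32, VIM 1.86). Also in NEUROG3 cells 11 of 15 pluripotency genes fell (median -0.815, 13 adjusted over the list alone, USP44 -1.43, DNMT3B -1.03, NANOG -0.98). SNAI2 cells lost 8 of 15 epithelial genes (median -0.823; 11 adjusted over the list alone; SPINT2 -0.86, EPCAM -1.75). In MITF cells 6 of 10 p53 targets rose (median 0.849; 8 adjusted over the list alone; CDKN1A 1.78, GADD45A 1.15), and in NEUROD1 cells 4 of 7 neuronal genes (median 0.914; STMN2 4.08, DLL3 1.61).

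The test with the first vector over 5946 genes and 55 genotype sets called 3342 pairs, 2324 higher and 1018 lower, and 36 sets had at least 20. Without replicate 2 NEUROG3 had 293 called genes and NEUROD1 114, and without replicate 1 MITF had 186. Fry called 147 of 1265 list and set pairs, 99 also with an estimated correlation.

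With the NoHygro vector MITF cells (279 cells, 876 genes) gained the actin bundler LCP1 (5.88, SE 0.40), IGFBP7 (5.38, SE 0.21), HTN1 (5.36, SE 0.48) and the homeobox gene MSX1 (5.31, SE 0.40), and FGF17 fell by 3.98 (SE 0.34). ASCL5 cells (173 cells, 510 genes) gained the neurotrophin receptor NGFR (5.94, SE 0.27), TFF3 (5.68, SE 0.20), IGFBP5 (5.60, SE 0.32) and the CGRP gene CALCA (5.20, SE 0.28), and FGF8 fell by 1.92 (SE 0.34). NEUROG1 cells (130 cells, 318 genes) gained BGN (4.61, SE 0.38), the peptide gene GRP (4.61, SE 0.51), MFAP4 (4.31, SE 0.18) and ASS1 (3.89, SE 0.17), and B3GNT7 fell by 1.96 (SE 0.33).

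In NoHygro MITF cells 10 of 13 mesendoderm genes fell (median -1.28; NODAL -1.28, GSC -3.94, EOMES -1.77; adjusted p = 2.69e-06) and 11 of 16 pluripotency genes (median -0.845; 15 adjusted over the list alone; TDGF1 -1.49, DNMT3B -1.26), while 6 of 11 p53 targets rose (median 0.513; GDF15 5.02). The BMP and ID list was called higher in these cells at a mean of -0.171 and a median of 0.440 (adjusted p = 0.455 with an estimated correlation), and the trophoblast list higher at a mean of -0.582 and a median of 0.510 (adjusted p = 0.689 with an estimated correlation). ASCL5 cells gained 6 of 9 BMP and ID genes (median 1.64; ID3 2.56). NEUROG1 cells gained 10 of 12 mesenchymal genes (median 1.75; VIM 2.42, TAGLN 2.12, COL1A1 2.93) and 3 of 7 neuronal genes (HES6 2.12, DLL3 2.97).

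The test with the NoHygro vector over 8736 genes and 19 sets called 3633 pairs, 2362 higher and 1271 lower, and 14 sets had at least 20. Without replicate 1 it called 733 (218 for MITF, 119 for ASCL5, 73 for NEUROG1) and without replicate 2 it called 518 (129, 71 and 38). Control cells of the vectors differed in 235 of 10446 genes, 53 higher and 182 lower with NoHygro: CDA rose by 1.14 and BMP4 fell by 2.10, both chosen after their values were seen. The 235 became 147 without replicate 2 of the first vector, 27 without NoHygro replicate 1 and 359 without NoHygro replicate 2, and 256 (224 of them the same) without cells that failed a filter on total counts and mitochondrial share. NoHygro replicate 1 had a median mitochondrial share of 14.5%, and mitochondrially encoded genes lay higher with NoHygro by a median of 1.21 (6 of 13 adjusted over the list alone, list adjusted p = 0.380), so a part of cell quality in this difference is not excluded. The groups did not overlap for all 235, which adds no support, as these genes were called on the same libraries. No list passed between vectors (lowest adjusted p = 0.0938).

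In the single sample of MYC forms and KLF family members no test was made, as there was 1 library. KLF17, an early embryo factor, had TFF3 at a ratio of 63.3 to the control (counting interval 23.6 to 239), ARGFX at 38.9 and S100A14 at 29.96. KLF4 had HAND1 at 11.8 (7.35 to 19.6), APLNR at 8.70, LEFTY2 at 8.01 and RARRES2 at 0.139. MYC had RGS10 at 2.40, PSMB10 at 2.07 and the transferrin receptor gene TFRC at 2.07. Mesendoderm genes lay below the control in all 14 MYC forms (median log2 ratio of MYC -2.25, Thr58Ala -3.19) and above it in 15 of 17 KLFs (KLF4 1.5), with KLF17 at -1.22 and KLF16 at -0.318.

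Of 527 list and construct pairs over 31 constructs, 166 lay outside the central 95% of 10000 random lists, 73 above and 93 below. For independent pairs and members 26.35 would lie outside. Random lists drew each member alone and all constructs shared the control cells, so 26.35 is not the number that chance gives here. Mesendoderm medians were below that range in 10 MYC forms and above it in 14 KLFs. MYC targets were above it in 5 of 14 MYC forms and below it in 9 of 17 KLFs. The MYC and KLF cells shared the same control cells, and 0 cells carried both a KLF and a MYC form. The mesendoderm genes summed to 117 CPM in MYC cells, 363 in control cells and 581 in KLF cells, so ratios to this control are not shown to be effects of the constructs. Among the control cells they summed to 342 CPM with mCherry and 421 CPM with mCherry-int-ctrl.

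**Figure D3:**
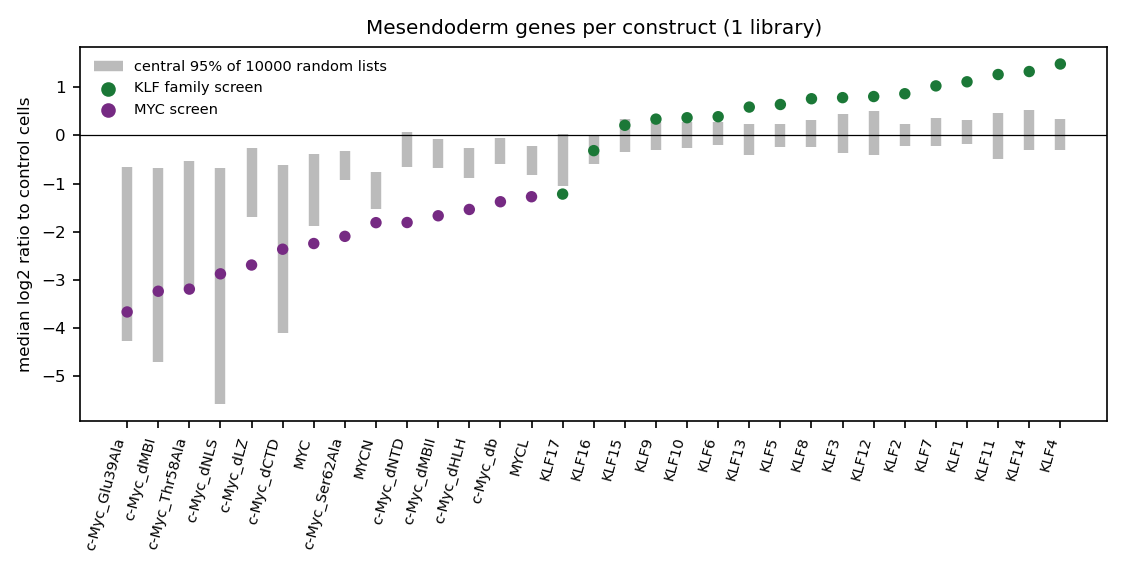
Median log2 ratio to the control of the mesendoderm list (y axis) for each MYC form and KLF (x axis), with bars for the central 95% of 10000 random lists matched on expression, 1 library. All 14 MYC forms lie below 0, and 15 of 17 KLFs above it.

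Barcode shares in hPSC gDNA against the plasmid were taken as fitness, though nothing here separates growth from other changes between plasmid and cells. The Hedgehog effector GLI1 fell by 2.52 (SE 0.13, n = 4 libraries, edgeR adjusted p = 8.04e-06), the endoderm factors FOXA1 by 1.56 (SE 0.20) and GATA6 by 1.39 (SE 0.15), the ETS factors ERG by 1.38 (SE 0.12) and FLI1 by 1.36 (SE 0.12), and MYCN by 1.32 (SE 0.16). ASCL3 rose by 1.47 (SE 0.18), LMX1A by 1.40 (SE 0.18), SNAI2 by 1.22 (SE 0.25), FOXP1 by 1.10 (SE 0.19) and MYCL by 0.80 (SE 0.20). OTX2 rose by 0.99 (SE 0.18) from 13 plasmid reads only. The mCherry barcode itself rose by 0.75 (SE 0.18). Scaled to it the gains were smaller: ASCL3 0.72, LMX1A 0.65 and FOXP1 0.34 were called, SNAI2 (0.48), OTX2 (0.25) and MYCL (0.05) were not.

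**Figure D4:**
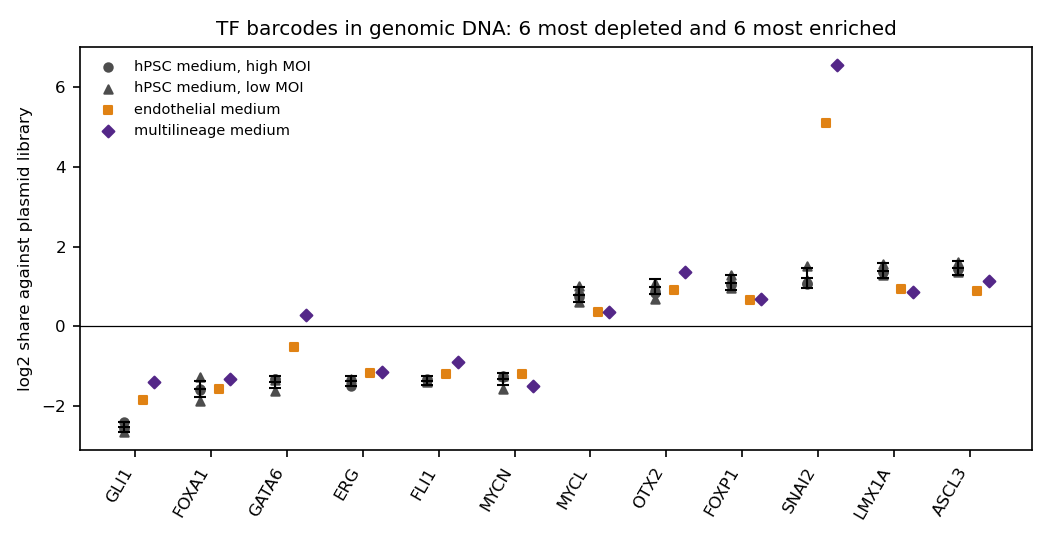
Log2 share of a barcode against its plasmid share (y axis) for the 6 most depleted and 6 most enriched TFs (x axis), with the 4 hPSC libraries as points beside the fitted value and its SE, endothelial medium as squares and multilineage medium as diamonds. GLI1 lies lowest at a fitted -2.52 and ASCL3 highest at 1.47 in hPSC medium.

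Of 62 barcodes, 26 passed in hPSC medium, 16 lower and 10 higher. With the nearly identical high MOI libraries summed 21 passed, the named ones among them. Scaled to the mCherry barcode, 47 passed, 44 lower and 3 higher, so the split between losses and gains depends on the scaling. Between high and low MOI edgeR called 0 barcodes, with 0 at an unadjusted p under 0.05, and DESeq2 called 0 with 3 at that level. Without replicate 3 edgeR called 38 and without replicate 4 it called 42. The high MOI libraries differed from each other by an SD of 0.0563 (log2 share) and the low MOI libraries by 0.454. Over 48 TFs, fitness and the number of called genes in hPSC medium were not related (Pearson r = 0.106, permutation p = 0.455; Spearman rho = -0.217, permutation p = 0.137; adjusted p over 8 relations 0.697 and 0.219). Without the 2 TFs farthest from the median fitness r was 0.104. With the root mean square fold change in place of the number of called genes r was -0.802 (permutation p = 1e-05, the smallest these permutations can give), and -0.0775 given the number of cells. Against hPSC gDNA, compared only after the values were seen, SNAI2 was higher by 3.89 in endothelial and by 5.32 in multilineage medium, and ONECUT1 by 2.97 and 4.37, with 1 library each and so no measured spread in these media. Those gains held with the total-count and mCherry scalings too (SNAI2 3.19 and 4.07, 3.82 and 5.62).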

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

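Of the tests below, those on outgrowth of SNAI2 cells, on other cultures or amplification, and the comparison of barcodes in the differentiation media with hPSC medium were chosen only after the result was seen.

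In 9 of 61 barcodes 1 of the 4 hPSC gDNA libraries lay far from the others (log2 against the plasmid), where chance gives about 1 in 20, or 3.1. The SRY barcode was left out of these 61, though low MOI replicate 3 lay far from the others for it too (0.339; others 0.0718 to 0.115). Low MOI replicate 3 was lowest for FOXA2 (-1.70; others -0.98 to -0.87), MYCN (-1.57; others -1.26 to -1.24), ONECUT1 (-0.59; others -0.23 to -0.21) and NEUROG3 (-0.52; others -0.19 to -0.12). It was highest for HOXA11 (0.54; others 0.16 to 0.20), MYOD1 (0.54; others 0.24 to 0.28) and HOXA10 (0.80; others 0.50 to 0.54). Low MOI replicate 4 was lowest for GATA6 (-1.61; others -1.33 to -1.31) and LHX3 (-0.02; others 0.20 to 0.23). The low MOI libraries differed from each other by an SD of 0.454 and the high MOI libraries by 0.0563, while the chance number takes libraries of like spread, so 9 against 3.1 does not show more than chance.

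TF effects differed from those in hPSC medium by a direct test for these numbers of 9259 genes. In endothelial medium they were KLF4 44 (3 to 82 with 1 library left out), CDX2 25 (1 to 79), ONECUT1 15 (1 to 34), NEUROD1 8 (1 to 17), MITF 3 (0 to 21), ATF7 2 (0 to 4), OTX2 2 (0 to 5), MYOG 1 (0 to 7) and SNAI2 1 (0 to 1). In multilineage medium they were KLF4 170 (9 to 261), CDX2 55 (8 to 99), MITF 44 (4 to 114), ATF7 21 (2 to 52) and OTX2 9 (0 to 13). By the labels estimated MOI changed together with the medium, so these differences are not assigned to the medium alone.

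Barcodes whose change from the plasmid differed from hPSC medium numbered 9 in endothelial and 9 in multilineage medium, all higher. Each of these media had 1 library, taken to vary like the hPSC libraries, so these numbers do not measure replication. SNAI2, KLF4, ONECUT1, GATA4, GATA6 and GLI1 were in both sets. CDX2, NEUROD1 and TBX5 were in the endothelial set only and FLI1, GATA2 and MYOG in the multilineage set only. With total counts as the scaling 44 barcodes differed in endothelial medium, 40 of them lower, and 58 in multilineage medium, 55 of them lower. Only SNAI2, KLF4 and ONECUT1 were then higher in both media, while GATA4, GATA6 and GLI1 were higher in both scaled to the control barcode but not with total counts.

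SNAI2 made up 35.0% of endothelial and 54.3% of multilineage barcode reads against 3.84% in hPSC medium, but of cells with exactly 1 construct 5.54 and 1.76% in the endothelial and 1.26 and 1.61% in the multilineage libraries (3.48% in hPSC medium). SNAI2 cells that show the SNAI2 expression change, hidden among cells without an assignment, are argued against in endothelial medium only, as multilineage medium was not tested. The cells without an assignment carried a median fraction of -0.045 of the SNAI2 change, and -0.252 in the other library (2056 and 2024 cells). Cells that carry SNAI2 without this change would escape the test, so it cannot decide on them. The SNAI2 share of cells was at most 1.59 times its hPSC share in 4 libraries, so the sequenced cells showed no gain of the size seen in gDNA. This test of outgrowth in every culture reused cell shares that are part of the pattern, so it could not decide. Gain in other cultures or in amplification stays open: with 1 gDNA library per medium these cannot be told apart. By the protocol gDNA came from cells that remained after loading. Which single-cell library a gDNA library goes with is not given in the sources used here.

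MITF had 205 called genes in multilineage medium from 17 and 10 cells. Damaged cells are argued against, with a mitochondrial share at most 0.743 times and UMIs 1.42 and 1.26 times those of control cells. Chance from few cells is argued against, with at most 5 calls in 20 draws of as many control cells. A response to MITF shared with other cultures stays open. The sign was the same for 73.3% of these genes with the first neuronal vector, 80.5% in endothelial and 68.9% in hPSC medium. With NoHygro it was the same for 57.5% (95% binomial interval over genes 50.1 to 64.7). That interval takes genes as independent, which they are not, and measures no spread between libraries. A shared response and one of this medium cannot be told apart.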

How the results depend on the processing

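Tests with summed high MOI libraries, with the cell filter between vectors and with other scalings of the barcodes in the differentiation media were chosen after seeing the data.

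Numbers of called pairs or genes depended on the processing more than their direction did, and the cause was not tested unless given. With DESeq2 size factors in place of TMM no named gene lost its call or changed direction. The DESeq2 Wald test lost 64 named results and no library block lost 32. Without a library block, hPSC calls were 514 (4 TFs with at least 20 calls), endothelial 400 (7), multilineage 129, first vector 281 and NoHygro 739. With the DESeq2 Wald test, hPSC calls were 836 (10 TFs), endothelial 412 (9), multilineage 274, endothelial against hPSC medium 602, endothelial against multilineage medium 1817 and between vectors 74. All cells carrying a TF, which are more, gave 3476 in hPSC (38 TFs) and 3462 in endothelial medium (30). In multilineage medium they gave 578 (6 TFs), below the 652 of the main test. No filter on low counts, which tests more genes, gave 4260 in endothelial (33 TFs), 1757 in multilineage medium (10), 7476 with the first vector and 14 between vectors. At least 20 cells, which tests fewer TFs, gave 16 TFs in hPSC and 906 calls (6 TFs) in endothelial medium. In multilineage medium only KLF4 (30 and 68 cells) was left to test, so the 1198 calls there are those of KLF4 alone. KLF4 had 258 of the 652 calls in the main test of 13 TFs. The cause of this rise was not tested. Limma voomLmFit with sample weights gave 23 TFs in endothelial medium, 1372 calls (7 TFs) in multilineage medium and 6444 with the first vector, and BH within each genotype 1288 in multilineage medium.

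All single cells in place of control cells, which are more, gave 1913 genes between endothelial and hPSC medium, 7963 between multilineage and hPSC medium, 4452 between endothelial and multilineage medium and 660 between vectors. Samples of a pair share only a number: the correlation within pairs was 0.147 between endothelial and multilineage medium and 0.0199 between vectors, and a replicate block gave 3653 and 523 genes.

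Fitness calls were 47 scaled to the control barcode, 21 with summed high MOI libraries and 41 with summed low MOI libraries, which removes their spread, and the MOI comparison then gave 19. Barcodes that differed from hPSC medium were 44 in endothelial and 58 in multilineage medium with total counts, and 16 and 14 scaled to the control barcode. The relation of fitness to the number of called genes (r = 0.106) reversed to r = -0.802 with the root mean square fold change, which follows the number of cells: given that number the partial r was -0.0775. List calls in the 3 TF screens were 105, with 74 by camera with an estimated correlation and 107 with size factors. Pairs outside the random range in the MYC and KLF sample were 166, with 148 at 20 cells and 170 as means over cells.

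With 1 library left out, and the lone library of a group assumed to vary like the other groups, calls were 286 to 299 in hPSC medium (2 to 4 TFs), 1093 to 1928 in endothelial (13 to 17) and 306 to 659 in multilineage medium (4 to 5), 2824 to 3650 with the first vector and 518 to 733 with NoHygro. Medium comparisons gave 146 to 1314 (endothelial against hPSC), 3020 to 5613 (multilineage against hPSC) and 1114 to 2790 (endothelial against multilineage), and the vectors 27 to 359. Interactions gave 39 to 708, fitness 21 to 36 and MOI 0 to 42. Changes of 2-fold were recovered for 23.3 to 35.5% of simulated genes in the TF and neuronal screens.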

Other observations

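Of the tests below, both tests on mesendoderm genes in MYC and KLF cells were chosen only after the result was seen.

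Lists moved in many TFs beyond those named. In hPSC medium the pluripotency list fell in 9 of 49 TFs (7 of them also with an estimated correlation), the BMP and ID list rose in 7 (7), the neuronal list in 6 (4), the mesendoderm list in 5 (5) and the HOX list in 4 (4). In endothelial medium the skeletal muscle list rose in 6 of 43 TFs (6), the muscle factors MYOD1 (median 2.38) and MYOG (1.59), and ASCL4, KLF4, NEUROD1 and SPIB. With the first neuronal vector the pluripotency list fell in 24 of 55 genotype sets (22 also with an estimated correlation), while the BMP and ID list rose in 25 (22), the mesenchymal list in 21 (15) and the HOX list in 13 (8). Sets of a screen share their control cells, so these counts are not independent of each other.

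In the single MYC and KLF sample other lists also differed from the shared control. BMP and ID genes were below the random range in 12 of 14 MYC forms and NOTCH genes in 9. MIXL1, a primitive streak gene, was at 9.89 CPM in MYC cells, 77.7 in control cells and 118 in KLF cells, and NODAL at 51.9, 118 and 159. Cells that carried a MYC form together with a control construct had 170 CPM of the mesendoderm list and cells with a KLF and a control construct 512, against 363 in cells with a control construct alone.

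Mesendoderm genes lay below the shared control in MYC cells and above it in KLF cells. A control construct occurred together with a MYC form in 296 cells and with a KLF in 94, so it was found with both sets of constructs. Control cells that mix 2 cultures which differ without any construct stay open. Over genes that differ more than 2-fold between MYC and KLF cells, the control lay in between for 74.3% (84 of 113), at a median of 0.370 of the way. Constructs with opposite effects would give that too. An effect of MYC itself stays open as well: in the TF screen the list's median in MYC cells of hPSC medium was 0.35, but MIXL1 was only 4.89 and 5.52 CPM in control cells there, so the 2 cannot be told apart. The forms below the control in the single sample included those labelled dHLH, dLZ, db, dNLS and dNTD. Whether these forms keep MYC function was not measured here.

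Plasmid reads were few for 2 TFs. OTX2 had 13 plasmid reads but 68 cells in hPSC medium, and HNF4A had 18 plasmid reads and 0 cells. Fitness followed the number of cells over 48 TFs (r = 0.902; permutation p = 1e-05, the smallest these permutations can give), so the barcode and the cell counts of hPSC medium went together.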
